A study of Mus musculus with 12 samples.

How the data were processed

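PolyA RNA was sequenced from the mammary gland of 12 lactating C57BL/6 mice, 7 knockout (KO) for Btn1a1 and 5 wild-type (WT), with 1 library per mouse. Per the labels, the libraries were made with an Illumina TruSeq mRNA kit and read as pairs. Per the submitters' processing notes, the tools used upstream were bcl2fastq 2.17, Trimmomatic 0.33, STAR 2.5.2b, RSEM 1.3.0 and limma 3.34.5. The same notes name the builds mm10 and hg19 without saying what each was used for, and the annotation used by the authors is not given in the sources used here.

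The authors deposited 1 table of 11834 genes, and its 12 library columns hold log2 CPM, read counts scaled to a common library total, as voom gives them. These deposited log2 values had already been quantile-normalized. Across the 12 libraries, 67.1% of ranks differed by less than 0.01 log2, and the linear values of each library summed to between 988803 and 988808 CPM. The table also holds the authors' log2 fold change of KO against WT, a score that is the moderated t statistic of the authors' limma fit, and the authors' p-value with its adjusted p-value. How genes were filtered before the table was made is not given in the sources used here. Read counts were not given, so count models were not used.

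Total counts per library are not in the table. An approximate depth was estimated from the step between neighbouring values, between 0.5 and 8 CPM, that at least 8 genes of a library share, because such values stem from neighbouring whole counts. Normalization between libraries changes that step, so the estimate is rough, and no counting interval is given for any gene.

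The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 by genotype alone, with eBayes using the trend and robust options. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all 11834 genes, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit, and standard deviations (SD) are between libraries of a group. Differences of a single value between groups were tested by exact two-sided permutation of the group labels.

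Before the data were examined, 32 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 5 measured members, 27 of the 32, were tested by camera with a preset correlation between genes of 0.01, adjusted over the 27 lists. Beside it stand camera with an estimated correlation and fry, both from limma. The score of a list in a library is the mean of its members' log2 CPM minus the WT mean. An exact permutation test of these scores was added after the data were seen.

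The rule for named genes took Btn1a1 first. It then took the 10 called genes with the largest log2 fold change in each direction, among genes with an ordinary symbol and a mean of at least 1 log2 CPM. From each list it took up to 4 members of smallest adjusted p, called or not, and up to 6 for the milk protein, milk fat globule and apoptosis lists. Genes named outside the rule are said to be so.

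Coordinates come from GENCODE M21 (mm10), joined by gene symbol, which matched 11468 of the 11834 genes (96.9%). Calls within 10 Mb of Btn1a1 were compared with those elsewhere by Fisher's exact test. Outlying libraries were sought by Dixon's ratio in each group of 5 or 7 values at the 95% level. Python 3.11.15 joined the annotation and drew the figures with matplotlib 3.10.9.

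The procedure was tested on simulated data of 7 and 5 libraries. It recovered 89 of 100 genes with a log2 change of 1 and 47 of 100 with a log2 change of 0.5, with 5 false calls (3.55% of calls). The changed genes were not drawn from the most variable genes. The simulated list that was shifted was called, as was 1 of the 19 lists that were not. Genes were simulated independently of each other, so this does not show how the list test behaves when genes of a list are correlated.

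The alternatives tried for genes were a block of replicate numbers, lactation day as a covariate, day 10 libraries alone, quantile normalization and median centring, stricter filters, eBayes without trend and robust options, library weights, leaving out each library, stricter thresholds and the authors' statistics. For lists they were an estimated correlation, a preset correlation of 0.05, fry, ranks and the same changes of design. Cyclic loess, a muscle marker covariate and a depth covariate were chosen after seeing the data, as were a restriction to the more highly expressed genes and the normalizations for lists. Pseudocounts do not apply to log2 values, and a fit without a filter could not be had because the table was filtered when deposited. All 12 libraries were used.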

Results

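Gene expression was measured by polyA RNA sequencing in the lactating mammary gland of mice that lack butyrophilin 1a1 (Btn1a1), a membrane protein of the milk-secreting cell that coats secreted fat globules, and in wild-type mice. The 12 libraries came from 7 KO and 5 WT mice, all in lactation 1. Of these, 5 KO and 3 WT glands were taken on day 10. WT replicates 2 and 3 were taken on days 9 and 11, and KO replicates 3 and 4 on days 8 and 11. The estimated depth ran from 17.1 M to 30.4 M reads in WT (mean ± SD of 26.1 ± 5.33 M, n = 5) and from 23.2 M to 34.7 M in KO (27.4 ± 4.07 M, n = 7; exact permutation p = 0.649). The 8 most abundant genes, all above 14 log2 CPM, took 70.7% of the CPM sum.

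The 1st comparison asked whether the targeted gene was lost. Btn1a1 fell from 11.07 ± 0.09 log2 CPM in WT (SD, n = 5) to 5.63 ± 0.30 in KO (SD, n = 7). That is a log2 change of -5.43 (SE 0.13), or 43.2-fold lower. On the linear scale the levels were 2146 CPM in WT and 49.6 CPM in KO, so 2.31% of the WT level was left, and the 7 KO libraries held between 34.2 and 65.1 CPM. The KO level still lay above that of 92.7% of the genes in the table. The gene lies on mouse chromosome 13 from 23456992 to 23465901 (mm10) and has 8 annotated exons. All 7 KO libraries lay below all 5 WT libraries (adjusted p = 5.2e-13; exact permutation p = 0.00126, the smallest this design can give). In WT, 4 of the 5 libraries held the same value of 11.03, because quantile normalization gives a fixed value to each rank. Which exons the remaining reads came from cannot be read from a table of gene values.

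The 2nd comparison asked which genes differ between KO and WT glands. Saa2 and Saa1, which encode acute-phase apolipoproteins, rose most among the named genes, by log2 changes of 7.98 (SE 1.65, adjusted p = 0.0173) and 7.32 (SE 1.58, adjusted p = 0.0203). Saa2 went from -0.80 ± 1.11 log2 CPM in WT (SD, n = 5) to 7.18 ± 3.58 in KO (SD, n = 7). Orm2, an acute-phase plasma glycoprotein, rose by 4.21 (SE 0.70, adjusted p = 0.00696), Lrg1, a leucine-rich glycoprotein induced in inflammation, by 3.75 (SE 0.71, adjusted p = 0.0120), Defb1, an antimicrobial beta-defensin, by 3.73 (SE 0.48, adjusted p = 0.00222), and C4b, a complement component, by 3.67 (SE 0.55, adjusted p = 0.00447). The other rises of this size were Clca3a2, of a chloride channel regulator family, by 4.99 (SE 0.65), Cdhr1, a cadherin-related protein, by 4.93 (SE 0.65), Basp1, a membrane-attached signalling protein, by 3.67 (SE 0.64), and Spp1, which encodes the secreted phosphoprotein osteopontin, by 3.52 (SE 0.74). Their adjusted p ran from 0.00289 to 0.0178. For 9 of these 10 genes, all except Spp1, each KO library lay above each WT library. Saa1 with Saa2, Orm1 with Orm2 and Clca3a1 with Clca3a2 are close paralogs that can share reads, so the split between members of a pair is uncertain.

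Among the 9 largest falls after Btn1a1, Cbs, the first enzyme of transsulfuration, fell by 2.09 on the log2 scale (SE 0.45, adjusted p = 0.0173), from 4.04 ± 0.44 log2 CPM in WT (SD, n = 5) to 1.95 ± 1.00 in KO (SD, n = 7). Aldh1l2, a mitochondrial folate enzyme, fell by 1.44 (SE 0.31, adjusted p = 0.0162), and Ero1lb, an endoplasmic reticulum oxidase of disulfide bond formation, fell by 1.18 (SE 0.13, adjusted p = 0.00044). Sfrp2, a secreted modulator of Wnt signalling, fell by 1.18 (SE 0.18, adjusted p = 0.00304). Atp12a, a proton-potassium pump, fell by 1.37 (SE 0.28, adjusted p = 0.0123), and Lrrc26, a subunit of potassium channels, fell by 1.24 (SE 0.25, adjusted p = 0.0103). The calls of Serpina11 (log2 change -1.56), Pnpla3 (-1.30), a lipid droplet hydrolase, and Crhr1 (-1.18), a receptor of corticotropin-releasing hormone, had adjusted p of 0.0446, 0.0297 and 0.0463. Leaving out 1 library ended the call of Serpina11 for any of WT replicates 1 to 5 and KO replicates 1 to 4, with an adjusted p of up to 0.101. It ended that of Pnpla3 for any of WT replicates 1 to 4 (up to 0.0682), and that of Crhr1 for any library except KO replicates 3 and 7 (up to 0.106).

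In all, 1108 of the 11834 genes were called (9.36%), 573 higher and 535 lower in KO. The balance of directions turned in the authors' statistics, with 539 higher and 602 lower. It also turned without KO replicate 3 (575 higher, 582 lower), and with a mean of at least 1 log2 CPM (503 higher, 507 lower). So it did with the restriction to the more highly expressed genes (389 higher, 413 lower). All other alternatives gave more genes higher than lower, with 653 higher and 481 lower after cyclic loess, an alternative chosen after seeing the data. The median log2 change was 0.62 among those higher and -0.48 among those lower. With an absolute log2 change of at least 1 there were 186 genes, 148 higher and 38 lower. The KO and WT libraries did not overlap for 642 genes (5.43%, against 0.253% by chance). The authors' table has 1141 genes at the same threshold, and the 1047 genes called in both moved in the same direction in both. Saa2 and Saa1 are not past it there, with the authors' adjusted p of 0.179 and 0.0771, and here the Saa1 call ended without WT replicate 1 (adjusted p = 0.0545) or WT replicate 5 (adjusted p = 0.0508).

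On the 1st principal component, which held 37.2% of the variance, all 5 WT libraries lay at or below -19.2, and the KO libraries ran from -7.14 to 47.7. The count of genes called fell to 268 with day 10 libraries alone and to 277 with the muscle marker score as a covariate, and of 88 called genes that the naming rule took, 30 and 38 kept their call. It was 559 without WT replicate 1, 644 without WT replicate 2, 725 without WT replicate 3, 696 without WT replicate 5 and 724 without KO replicate 1. Genotype, breeding line and diet cannot be told apart here, because per the labels the mutant line was bred apart from the wild-type mice and the diet of each mouse is not given.

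**Figure D1:**
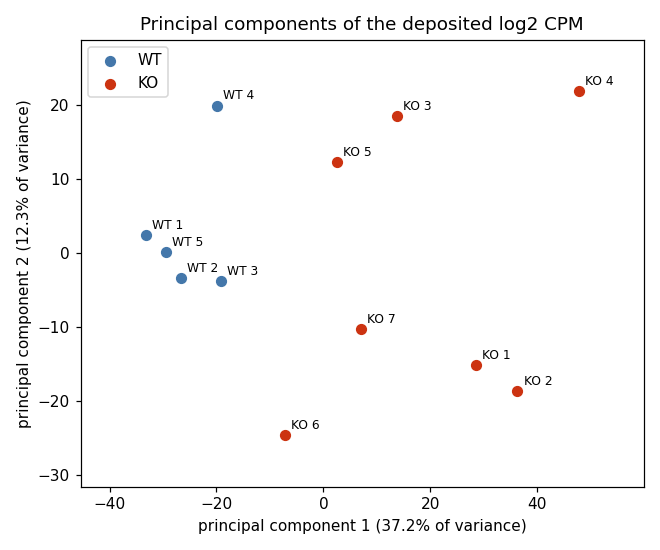
Principal components 1 and 2 of the deposited log2 CPM, with 37.2% and 12.3% of the variance, for 5 WT and 7 KO libraries, each point a library. All WT libraries lie at or below -19.2 on component 1 and all KO libraries at or above -7.14.

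**Figure D2:**
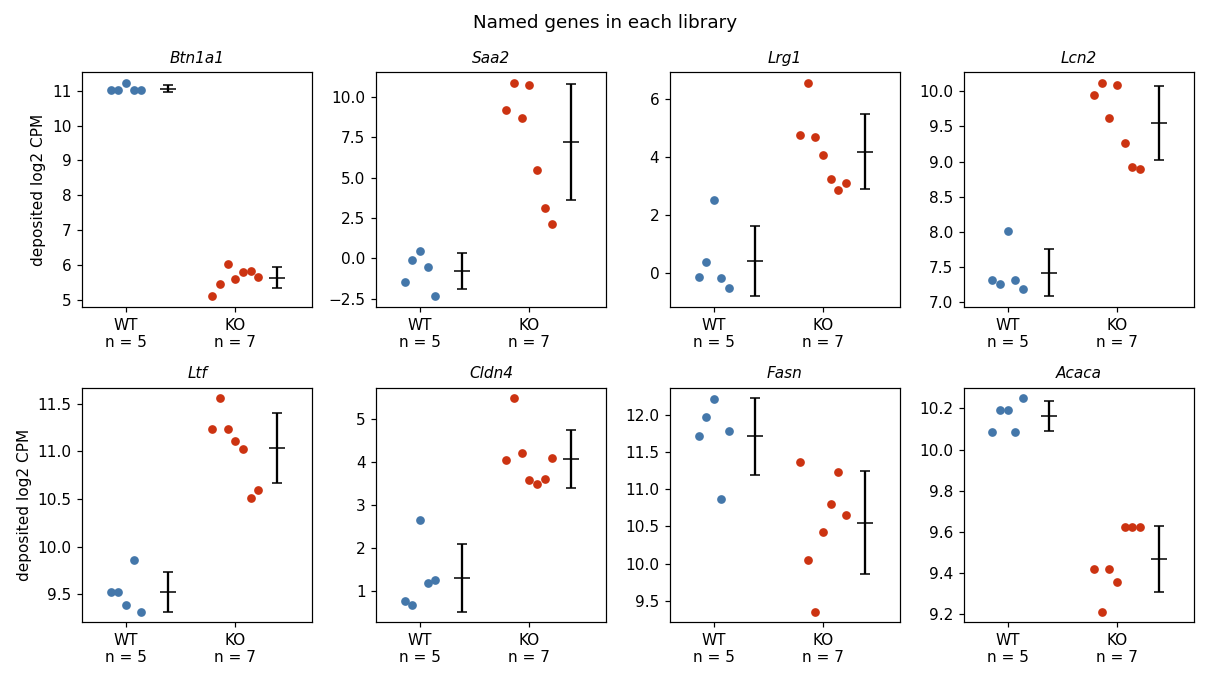
Deposited log2 CPM of 8 genes in each library of WT (n = 5) and KO (n = 7), with the mean and SD of each group beside the points. Btn1a1 fell by 5.43 on the log2 scale, Lcn2 rose by 2.13 and Acaca fell by 0.69.

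The 3rd comparison asked whether genes of 27 fixed lists moved apart from the other genes. Genes of the involution Stat3 list, linked to Stat3 signalling in mammary epithelium when milk removal stops, stood highest by this test. The list is not made of Stat3 targets alone, since it also holds Lif, which acts upstream of Stat3. Of 28 measured members 15 rose, 0 fell and 13 did not pass, and 17 rose when adjusted over the list alone. Lcn2, an iron-sequestering lipocalin, rose by 2.13 (SE 0.24, adjusted p = 0.000841), Timp1, an inhibitor of metalloproteinases, by 0.93 (SE 0.13, adjusted p = 0.00188), Lif, the cytokine that activates Stat3, by 2.82 (SE 0.41, adjusted p = 0.00217), and Atf3, a stress-induced transcription factor, by 2.10 (SE 0.31, adjusted p = 0.00265). Stat3 itself, named after its values were seen, rose by 0.50 (SE 0.14, adjusted p = 0.0406). Whether this call near the threshold holds when 1 library is left out was not tried. The median log2 change of the list was 0.98 (adjusted p = 1.7e-15 by camera, adjusted p = 0.233 with an estimated correlation). Its score was 1.65 higher in KO, and all 7 KO libraries lay above all WT libraries. Immediate early genes, 4 of which the Stat3 list also holds, gave 6 of 14 higher and 0 lower (8 higher adjusted over the list alone). Jun rose by 1.39 (SE 0.24), Junb by 1.29 (SE 0.25) and Fos by 1.14 (SE 0.24), all members of the AP-1 transcription factor family. The median was 0.58 (adjusted p = 3.8e-07; adjusted p = 0.233 with an estimated correlation). The skeletal muscle marker score was higher in KO as well, by 1.13, with 5 of 7 KO libraries above all WT libraries (exact permutation p = 0.122). So were the scores of macrophage markers, by 0.37 (6 of 7 above all WT libraries, exact permutation p = 0.00884), and of basal and myoepithelial markers, by 0.39 (6 of 7, exact permutation p = 0.00631).

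Of 24 measured mitotic genes, 16 rose in KO and 0 fell, and 23 rose when adjusted over the list alone. Ube2c, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose by 2.48 (SE 0.51, adjusted p = 0.0114), from -1.55 to 0.93 log2 CPM. Ccnb1 and Ccna2, cyclins of the G2 and M phases, rose by 2.53 (SE 0.55) and 2.24 (SE 0.48), and Kif20a, a kinesin of cytokinesis, by 1.38 (SE 0.30). The median of the list was 1.57 (adjusted p = 2.5e-14; adjusted p = 0.233 with an estimated correlation), and 6 of 7 KO libraries scored above all WT libraries, with KO replicate 5 among the WT values at -0.04. Mki67, named after its values were seen, was the member that did not pass over the list alone (log2 change 0.13, SE 0.15, adjusted p = 0.623), and its WT level of 5.68 log2 CPM was high already. DNA replication genes gave 7 of 22 higher and 0 lower, or 15 higher and 1 lower adjusted over the list alone. In this list 6 of 7 KO libraries scored above all WT libraries, while KO replicate 5 scored below all of them, at -0.20. Mcm4 and Mcm2, subunits of the replicative helicase, rose by 1.10 (SE 0.26, adjusted p = 0.0203, or 0.0533 without WT replicate 5) and 0.94 (SE 0.22, adjusted p = 0.0200, or 0.0542 without WT replicate 1 and 0.0514 without WT replicate 3). The list had a median of 0.79 (adjusted p = 4.1e-07; adjusted p = 0.329 with an estimated correlation). The muscle marker score was 1.13 higher in KO beside these lists too. Too few members of the mitosis, DNA replication and immediate early lists lay in the upper part of expression for a test there.

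Of 26 measured genes of fatty acid and triglyceride synthesis 0 rose in KO and 10 fell, while 16 did not pass, and 15 fell when adjusted over the list alone. Acaca, which makes malonyl-CoA, fell by 0.69 (SE 0.09, adjusted p = 0.0013), Elovl5, an elongase of polyunsaturated fatty acids, fell by 0.88 (SE 0.18, adjusted p = 0.0110), Agpat1, an acyltransferase of glycerolipid synthesis, fell by 0.55 (SE 0.11, adjusted p = 0.00919), and Elovl1, an elongase of long fatty acids, fell by 0.40 (SE 0.09, adjusted p = 0.0123). Fasn, the fatty acid synthase, named after its values were seen, fell by 1.15 (SE 0.33, adjusted p = 0.0464). That call lies near the threshold, and whether it holds when 1 library is left out was not tried. The list median was -0.38 (adjusted p = 3.8e-07; adjusted p = 0.233 with an estimated correlation). Its score was lower in 5 of 7 KO libraries than in any WT library. The muscle marker score was 1.13 higher in KO (exact permutation p = 0.122). Macrophage markers scored 0.37 higher (exact permutation p = 0.00884), and basal and myoepithelial markers 0.39 higher (exact permutation p = 0.00631). With the muscle score as a covariate the fatty acid list kept its call (adjusted p = 5.4e-07 by camera). No such fit was made with the macrophage or basal scores.

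Genes of milk fat globule secretion gave 1 of 15 higher and 3 lower, the same counts as adjusted over the list alone. Slc34a2, a phosphate transporter of the apical membrane, fell by 0.63 (SE 0.11, adjusted p = 0.00485). Plin2, a lipid droplet coat protein, fell by 0.51 (SE 0.12, adjusted p = 0.0167), Muc1, an apical mucin, fell by 0.59 (SE 0.14, adjusted p = 0.0187), and Adipor2, an adiponectin receptor, rose by 0.40 (SE 0.09, adjusted p = 0.0182). Without WT replicate 1 these last calls ended, at adjusted p of 0.0505, 0.0516 and 0.0506. Xdh, which binds Btn1a1 at the globule membrane and is named after its values were seen, had a log2 change of -0.21 (SE 0.12, adjusted p = 0.270). The list median was -0.21 (adjusted p = 0.0444; adjusted p = 0.255 with an estimated correlation), and its call ended without WT replicate 1 (0.0668), WT replicate 2 (0.0579), WT replicate 5 (0.0674), KO replicate 3 (0.0515) or KO replicate 4 (0.0501). It also ended with day 10 libraries alone (adjusted p = 0.0691), by ranks (0.0533), after cyclic loess (0.0505) and with the muscle covariate (0.0859).

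Milk protein genes gave 3 of 16 higher and 0 lower, also when adjusted over the list alone. Ltf, the iron-binding lactoferrin, rose by 1.51 (SE 0.17, adjusted p = 0.000383), and Wfdc18, a secreted whey-type protein, by 0.95 (SE 0.17, adjusted p = 0.00522). The call of Chil1, a chitinase-like protein, at 2.06 (SE 0.59, adjusted p = 0.0436) ended without any 1 of 9 libraries, all except KO replicates 5, 6 and 7, with an adjusted p of up to 0.105. Csn2 and Wap held the same value in all 12 libraries, 17.27 and 16.54 log2 CPM, because they kept the same rank. Csn1s1, Csn1s2a, Csn1s2b, Csn3, Glycam1 and Trf, the rest of the 8 most abundant genes, held 1 value each in all WT libraries and left it in KO replicates 1, 2 or 4 alone, so the levels of these 8 of the 16 members are largely fixed by the normalization. That also holds the list median near 0, and no absence of change can be read from it. The list median was 0.01 and the mean 0.28, and the list was not called by camera (adjusted p = 0.115), although all 7 KO libraries scored above all WT libraries (exact permutation, adjusted p = 0.0170). The list passed without KO replicate 2 (adjusted p = 0.0465). Cholesterol synthesis gave 0 of 22 higher and 1 lower (adjusted p = 0.115), but passed without WT replicate 5 (adjusted p = 0.00207), KO replicate 1 (0.00411) or KO replicate 2 (0.0465). Its called member Sqle, the squalene epoxidase, at -0.59 (SE 0.16, adjusted p = 0.0345), lost its call without any 1 of 8 libraries, all except WT replicate 5 and KO replicates 1, 3 and 6, with an adjusted p of up to 0.0940. The list of prolactin and Stat5 signalling gave 0 of 14 higher and 1 lower (adjusted p = 0.416). Gata3, a transcription factor of the luminal lineage, fell by 0.41 (SE 0.10, adjusted p = 0.0184, or 0.0507 without WT replicate 1 and 0.0508 without WT replicate 2).

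Interferon response genes gave 7 of 24 higher and 0 lower, and 16 higher adjusted over the list alone. Of the 7 KO libraries, 4 scored above all WT libraries for this list (exact permutation p = 0.0139). Irf7, a transcription factor of interferon genes, rose by 1.22 (SE 0.24, adjusted p = 0.00903), Oas1a, an antiviral synthetase, by 1.58 (SE 0.35, adjusted p = 0.0162), and Isg15, a ubiquitin-like modifier, by 0.86 (SE 0.20, adjusted p = 0.0162). The median was 0.62 (adjusted p = 1.1e-09; adjusted p = 0.255 with an estimated correlation). Macrophage markers gave 4 of 13 higher and 0 lower, and 8 higher adjusted over the list alone. Cx3cr1, a chemokine receptor, rose by 0.70 (SE 0.17, adjusted p = 0.0193, or 0.0504 without WT replicate 3), and C1qb, a complement subunit, by 0.46 (SE 0.11, adjusted p = 0.0201, or 0.0595 without WT replicate 1 and 0.0510 without WT replicate 3). Their median was 0.46 (adjusted p = 1.8e-05; adjusted p = 0.233 with an estimated correlation). Inflammatory cytokines and chemokines were not called (1 of 7 higher; adjusted p = 0.0552), although Cxcl1, a neutrophil attractant, rose by 2.70 (SE 0.49, adjusted p = 0.00736). That list passed without WT replicate 4 (adjusted p = 0.0432), WT replicate 5 (0.0117), KO replicate 2 (0.0465), KO replicate 4 (0.0379), KO replicate 5 (0.0431) or KO replicate 6 (0.0469). No B and plasma cell marker of 7 was called (adjusted p = 0.540), or had an unadjusted p under 0.05 in limma, though that list passed with day 10 libraries alone (adjusted p = 0.0366). The muscle marker score was 1.13 higher in KO beside these immune lists.

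Lysosome genes gave 3 of 21 higher and 0 lower, or 7 higher and 1 lower adjusted over the list alone. Ctsz, a cathepsin, rose by 0.86 (SE 0.14, adjusted p = 0.0038). The call of Ctss, another cathepsin, at 0.53 (SE 0.15, adjusted p = 0.0419) ended without any 1 of WT replicates 1, 2, 3 and 5 and KO replicates 1, 3, 4 and 5, with an adjusted p of up to 0.104. The median was 0.11 (adjusted p = 0.00477; adjusted p = 0.233 with an estimated correlation), and all 7 KO libraries scored above all WT libraries. The macrophage marker score was 0.37 higher in KO beside it, with 6 of 7 KO libraries above all WT libraries (exact permutation p = 0.00884), and the muscle marker score was 1.13 higher. The call of this list ended with day 10 libraries alone (adjusted p = 0.0750). Apoptosis genes gave 2 of 25 higher and 2 lower, or 9 higher and 2 lower adjusted over the list alone. Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 1.44 (SE 0.23, adjusted p = 0.0038). The median was 0.20 (adjusted p = 0.0163; adjusted p = 0.233 with an estimated correlation), and the call ended with day 10 libraries alone (adjusted p = 0.221), with the muscle covariate (0.0608) and without KO replicate 3 (0.0712). The lists not called here were p53 targets (2 of 18 higher; adjusted p = 0.641; median -0.01, mean 0.02), endoplasmic reticulum and integrated stress (1 of 23 higher and 4 lower; adjusted p = 0.555) and oxidative stress (4 of 16 higher and 3 lower; adjusted p = 0.437). Among them Mdm2, the ubiquitin ligase of p53, rose by 0.33 (SE 0.07, adjusted p = 0.0132). Phgdh and Psat1, enzymes of serine synthesis, fell by 0.88 (SE 0.13, adjusted p = 0.00228) and fell by 0.72 (SE 0.12, adjusted p = 0.00414), Shmt2, which links serine to the folate cycle, fell by 0.59 (SE 0.09, adjusted p = 0.00316), and the metallothioneins Mt2 and Mt1 rose by 3.33 (SE 0.41, adjusted p = 0.00188) and 1.53 (SE 0.29, adjusted p = 0.00987).

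Markers of basal and myoepithelial cells gave 8 of 14 higher and 0 lower, and 10 higher adjusted over the list alone. Actg2, a smooth muscle actin, rose by 1.00 (SE 0.15, adjusted p = 0.00304), Cxcl14, a chemokine, by 0.64 (SE 0.14, adjusted p = 0.0125), and Mylk, the myosin light chain kinase, by 0.37 (SE 0.08, adjusted p = 0.0123). Their median was 0.40 (adjusted p = 2.0e-06; adjusted p = 0.233 with an estimated correlation). The score of the 2 measured skin keratinocyte markers was 0.91 higher in KO beside them, with all 7 KO libraries above all WT libraries (exact permutation p = 0.00379), but it rests on Sbsn alone (log2 change 2.06), since Krt10 had -0.24. Fibroblast and matrix markers gave 2 of 15 higher and 0 lower, also adjusted over the list alone, among them Postn, a matrix protein, which rose by 0.78 (SE 0.16, adjusted p = 0.0105). The other, Dpt, the matrix protein dermatopontin, at 0.53 (SE 0.16, adjusted p = 0.0499), lost its call without any 1 library except KO replicate 6, with an adjusted p of up to 0.128. Their median was 0.29 (adjusted p = 0.00173; adjusted p = 0.480 with an estimated correlation), and the call ended with the muscle covariate (adjusted p = 0.157). Skeletal muscle markers had a median of 1.25 (adjusted p = 0.000677; adjusted p = 0.497 with an estimated correlation), yet 0 of 12 were called in limma over all genes or adjusted over the list alone, and 0 had an unadjusted p under 0.05. Myl1, a fast muscle myosin light chain, had a log2 change of 1.43 (SE 0.66, adjusted p = 0.197). Their score ran from -1.62 to 1.01 in WT and from -1.12 to 2.89 in KO, a difference of 1.13 (exact permutation p = 0.122).

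The other marker lists were not called by camera. Epithelial junction genes moved both ways, with 3 of 19 higher and 3 lower (adjusted p = 0.535). Cldn4, a tight junction claudin, rose by 2.76 (SE 0.40, adjusted p = 0.00316), while Cldn8, another claudin, fell by 0.72 (SE 0.12, adjusted p = 0.00415), and Cgn and Tjp1, cytoplasmic proteins of tight junctions, fell by 0.73 (SE 0.11) and fell by 0.48 (SE 0.08). Luminal progenitor markers gave 2 of 11 higher, Lcn2 and Aldh1a3, a retinaldehyde dehydrogenase (adjusted p = 0.416; median -0.15, mean 0.39). Hormone-sensing luminal markers gave 1 of 5 lower, Esr1, the estrogen receptor, which fell by 0.62 (SE 0.13, adjusted p = 0.00941; list adjusted p = 0.666). White adipocyte markers gave 1 of 16 higher and 1 lower (adjusted p = 0.666; median -0.02), and Lep, the hormone leptin, rose by 0.95 (SE 0.17, adjusted p = 0.00522). Endothelial markers gave 0 of 12 higher and 1 lower, the VEGF receptor Kdr (list adjusted p = 0.416; median -0.14). Kdr fell by 0.57 (SE 0.14, adjusted p = 0.0234, or 0.0551 without WT replicate 1, 0.0638 without WT replicate 2 and 0.0558 without WT replicate 4). The list became a call with the muscle covariate (adjusted p = 0.0188). Mitochondrially encoded genes gave 0 of 15 called (adjusted p = 0.571; median 0.02, mean -0.01). Brown adipocyte, skin keratinocyte, butyrophilin family, T and NK cell and neutrophil lists had 4, 2, 1, 1 and 0 measured members and were not tested by camera. Of the skin keratinocyte markers, Sbsn, which encodes suprabasin of the epidermis, rose by 2.06 (SE 0.37, adjusted p = 0.00620), and Krt10, a keratin of the epidermis, had a log2 change of -0.24 (SE 0.38, adjusted p = 0.731).

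By camera with the preset correlation, 13 of 27 lists were called, 11 higher and 2 lower. None held with an estimated correlation, where the smallest adjusted p was 0.233, and fry, which does not compare a list with other genes, called 10. By fry the DNA replication (adjusted p = 0.0648), apoptosis (0.0537), fibroblast (0.167) and skeletal muscle (0.199) lists did not pass, and milk proteins did (0.0134). With a preset correlation of 0.05 the milk fat globule (adjusted p = 0.115) and apoptosis (0.0984) calls ended. The exact permutation test of list scores, chosen after the data were seen, passed 16 of 27 lists after adjustment, 11 of them among the 13. The other 5 were milk proteins (adjusted p = 0.0170), inflammatory cytokines and chemokines (0.0227), and epithelial junctions, luminal progenitors and oxidative stress (0.0268 each), all with a higher score in KO. A few genes carry some of these scores. The medians were 0.01 for milk proteins, with 9 of 16 estimates above 0 and the largest those of Chil1, Ltf and Wfdc18, 0.01 for oxidative stress, with 8 of 16 above 0 and the largest those of Mt2 and Mt1, and -0.15 for luminal progenitors, with 5 of 11 above 0. The fibroblast (0.156) and skeletal muscle (0.184) lists did not pass it. When the libraries were regrouped at random into 7 and 5, 17 of 100 splits, the real one included, called at least 13 lists.

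**Figure D3:**
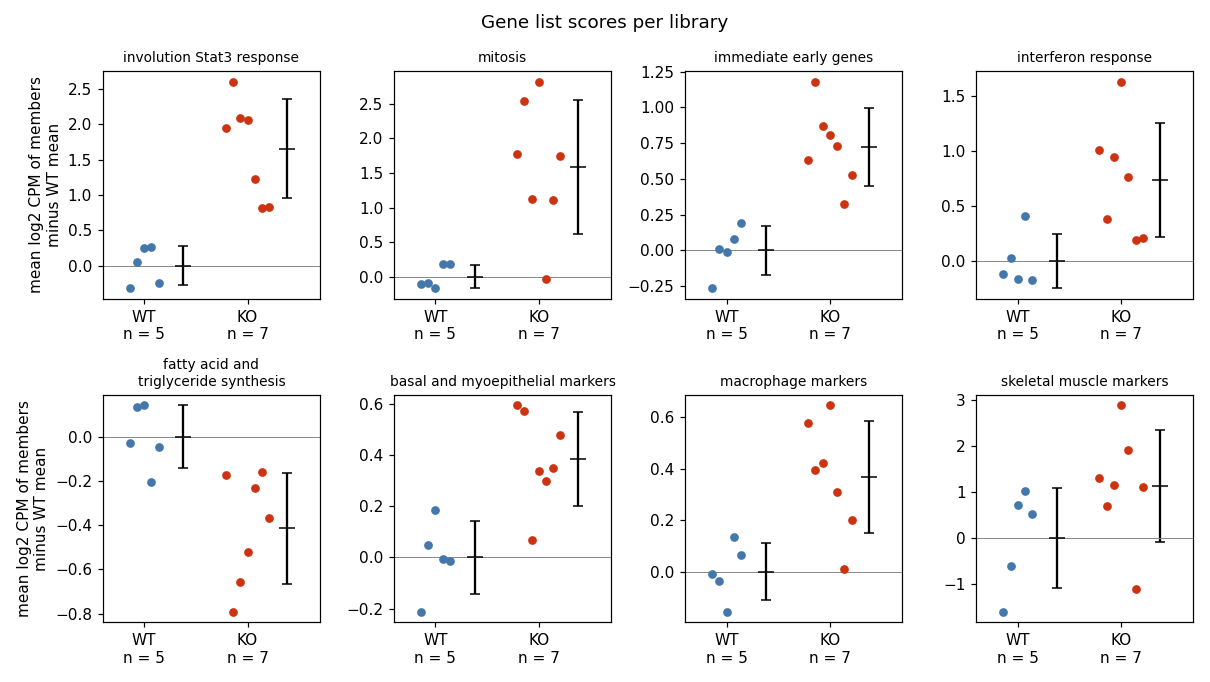
Score of 8 gene lists, the mean log2 CPM of the members minus the WT mean, in each library of WT (n = 5) and KO (n = 7), with the mean and SD of each group beside the points. All 7 KO libraries lie above all WT libraries for the involution Stat3 list, 6 of 7 for mitosis and 5 of 7 for skeletal muscle markers.

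The 4th comparison asked whether calls gather near Btn1a1, as sequence of a donor strain around a targeted allele could give. Of 52 genes within 10 Mb, 2 were called (3.85%), against 1080 of 11415 elsewhere (9.46%; odds ratio 0.383, 95% interval 0.0451 to 1.46, Fisher's exact p = 0.232). The 2 genes, named after their values were seen, were Ggps1, a synthase of isoprenoid chains, which fell by 0.52 (SE 0.12, adjusted p = 0.0162), and Gmds, an enzyme of GDP-fucose synthesis, which rose by 0.67 (SE 0.14, adjusted p = 0.00966). No more calls were found within 10 Mb of Btn1a1 than elsewhere. The interval includes 1, and the labels do not give the origin of the allele. Ero1lb, among the largest falls, also lies on chromosome 13, from 12565874 to 12611396, outside this window. Whether donor sequence reaches that gene was not tested.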

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

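The tests of lactation day, of the balance of cell markers and of the correlation among muscle markers were chosen after the results they bear on were seen, and so were the muscle and depth covariates as alternatives.

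Of 316 groups of values examined, 19 had a library far from the rest of its group, where chance flags about 1 in 20 groups, or about 16. Each ratio here is the gap from that library to the nearest other, divided by the range of its group. In WT replicate 3, Btn1a1 was highest at 11.23 log2 CPM with 11.03 in each of the other WT libraries (ratio 1). Quantile normalization tied those other libraries, so the Btn1a1 ratio would be 1 for a gap of any size. In the same library Lcn2 was highest at 8.01 (0.838), Bcl6 lowest at 1.85 (0.895) and Timp1 lowest at 3.22 (0.744). In WT replicate 5, Chil1 was lowest at -2.34 (0.731), Cd68 lowest at 0.97 (0.718), Ccna2 highest at 0.34 (0.741) and Ighm highest at 4.06 (0.836). In WT replicate 2, Rab18 was lowest at 8.06 (0.965), Jak2 lowest at 3.56 (0.933), and the white adipocyte score highest at 0.60 (0.773). In WT replicate 1, Nfkbia was lowest at 3.66 (0.713). In KO replicate 2, Basp1 was highest at 5.86 (0.615), Cldn4 highest at 5.48 (0.634) and Pnpla3 lowest at 2.13 (0.785). In KO replicate 6, Tek was lowest at 1.51 (0.620) and C1qa lowest at 3.62 (0.582). Plin2 was highest in KO replicate 3 at 9.69 (0.712), and Postn was highest in KO replicate 4 at 7.05 (0.610).

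The mitosis and involution Stat3 scores were higher in KO by 1.58 and 1.65, with 16 of 24 and 15 of 28 members called higher and an adjusted p of 0.233 for each list with an estimated correlation. With the muscle marker score as a covariate the KO terms stayed at 1.42 (SE 0.512) and 1.43 (SE 0.359), and with the estimated depth at 1.52 (SE 0.455) and 1.62 (SE 0.348), which argues against muscle in the sample or depth as the whole cause. With lactation day as a covariate they were 1.63 (SE 0.441) and 1.65 (SE 0.351), which argues against a trend with day as the whole cause. Among the 8 day 10 libraries the differences were 1.34 (exact permutation p = 0.107) and 1.59 (exact permutation p = 0.0357), so the mitosis difference there kept most of its size and did not pass. Loss of Btn1a1, the separately bred mutant line and the diet remain open, because the design holds no test that parts them.

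Of the myoepithelial markers 8 of 14 and of the macrophage markers 4 of 13 were called higher in KO, with an adjusted p of 0.233 for each list with an estimated correlation. A lower share of secretory luminal cells could give this if all other cell types rose alike. The score difference between myoepithelial and endothelial markers was 0.50 higher in KO (exact permutation p = 0.0177). That between macrophage and endothelial markers was 0.48 higher (exact permutation p = 0.00379). These values argue against an equal rise of all other cell types. Endothelial markers were the only reference tested. The fibroblast score was 0.32 higher in KO (exact permutation p = 0.0985), near the rises of the myoepithelial (0.39) and macrophage (0.37) scores. The outcome may thus depend on the reference, which was not tested with fibroblast markers, and a lower luminal share remains open. More cells of these types, higher expression within them, and differences of breeding line or diet also remain open.

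Skeletal muscle markers differed widely among libraries of both groups. Over deviations from the group means, the median correlation among 66 pairs of markers was 0.967 (lowest 0.750), across libraries, which is consistent with a varying share of muscle tissue in the samples. The difference between KO and WT in this score (1.13, exact permutation p = 0.122) did not pass. Whether muscle entered at dissection more often in 1 group remains open, and no biological explanation was tested.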

How the results depend on the processing

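The muscle covariate, depth covariate, cyclic loess, restriction to highly expressed genes and normalizations for lists were chosen after seeing the data. Of genes called (1108), 268 were called with day 10 libraries alone, which are fewer samples, 249 at an adjusted p under 0.01, 186 with an absolute log2 change of at least 1, and 277 with the muscle covariate, for which the cause was not tested. Leaving out 1 library gave 559 to 1327, and the other alternatives 802 to 1332. The replicate block gave 1083, of which 759 are among the 1108. Deviations of same-numbered WT and KO libraries correlated from -0.17 to 0.21, with 2 of 5 best matching their own number. This gave no clear sign that the numbers pair mice, but so few numbers cannot exclude it. Quantile normalization again (1108) and median centring (1106) could move little, since the values were already quantile-normalized. Btn1a1 stayed called throughout, at -5.50 to -5.34 without 1 library. Of lists called (13), 0 were called with an estimated correlation (adjusted p from 0.233), 11 to 16 without 1 library, and 10 to 13 otherwise. Calls near Btn1a1 numbered 0 of 16 within 2 Mb, 0 of 24 within 5 Mb and 11 of 117 within 20 Mb (odds ratio 0.996). Directions reversed only in genes not called: Ighm with the replicate block (0.0286) and without WT replicate 5 (-0.320 to 0.135 without 1 library), Tbx3 with day 10 libraries (0.32), with the muscle covariate (0.0476) and without WT replicate 2 (-0.271 to 0.0375 without 1 library), and Nfkbia with the muscle covariate (-0.0279); the cause was not tested. Of 88 named genes called, 64 to 85 kept their call without 1 library. Count tools, pseudocounts, no filter and the alternatives for a table of the authors' statistics alone were not run, because the values do not allow or need them. Depth per library is only estimated, which limits genes near the floor.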

Other observations

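Gene families by symbol, and the genes named in this paragraph and the next, were chosen after the data were seen, as were the tests of the Stat3 score against the mitosis and fatty acid scores.

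Of 187 families with at least 8 members, the aldehyde dehydrogenases (Aldh) gave 1 of 15 higher and 8 lower, with a median log2 change of -0.32 (adjusted p = 0.0191 by camera; adjusted p = 0.946 with an estimated correlation). Aldh2, the mitochondrial acetaldehyde enzyme, fell by 0.61 (SE 0.07, adjusted p = 0.000435), Aldh18a1, of proline synthesis, fell by 0.69 (SE 0.10, adjusted p = 0.00188), and Aldh4a1, of proline breakdown, fell by 0.51 (SE 0.10, adjusted p = 0.00736). Aldh1a3 rose by 1.45 (SE 0.30, adjusted p = 0.00987). The septins gave 3 of 8 higher (median 0.45, adjusted p = 0.0209), the Mcm family 5 of 9 (median 0.94, adjusted p = 0.0342) and the Tnfrsf receptors 2 of 9 (median 0.50, adjusted p = 0.0407), and the Zfp zinc finger genes 1 of 270 higher and 8 lower (median -0.13, adjusted p = 0.0342). Each of these families had an adjusted p of 0.946 with an estimated correlation. The Mcm family shares Mcm2 and Mcm4 with the DNA replication list, so it is not a separate result. Grouping by symbol also placed Mcm3ap in it, with a log2 change of -0.20 (adjusted p = 0.0998).

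Several genes outside the lists had some of the smallest p-values. Lamb3, a laminin chain of the epithelial basement membrane, rose by 0.83 (SE 0.08, adjusted p = 0.000248), while Lamb1, another laminin chain, fell by 0.61 (SE 0.08, adjusted p = 0.00151). Arpc1b, a subunit of the actin-nucleating Arp2/3 complex, rose by 0.80 (SE 0.08, adjusted p = 0.000261), and Elf3, an epithelial transcription factor, by 1.14 (SE 0.16, adjusted p = 0.00188). Arg1, the arginase of the urea cycle, rose by 2.31 (SE 0.29, adjusted p = 0.00115), from -0.48 to 1.83 log2 CPM. Ehhadh, a peroxisomal enzyme of fatty acid oxidation, fell by 0.74 (SE 0.10, adjusted p = 0.00188). Of 67 antisense genes tested, a class also picked after the data were seen, 0 were called higher and 6 lower. The share called in either direction is close to the 9.36% called over all genes. Over all genes, though, 573 were called higher and 535 lower, and whether the antisense genes differ in direction was not tested.

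Of 100 splits of the 12 libraries into 7 and 5, 1 gave as many called genes, the real split with 1108. The highest other gave 11, so chance is unlikely for the gene count, as far as 100 splits can show. For the count of lists, 17 of 100 splits gave at least 13 and the highest other gave 17, so chance cannot be excluded for the number of lists called by camera.

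Scores also differed among the 7 KO mice, and 3 relations were tested by exact permutation. The Stat3 and mitosis scores had r = 0.550 (p = 0.206, adjusted p = 0.206; rho = 0.571, p = 0.200), and r = 0.817 without the 2 libraries farthest from the median. The Stat3 and fatty acid scores had r = -0.736 (p = 0.0643, adjusted p = 0.0964; rho = -0.857, p = 0.0238), and r = -0.787 without 2. The Stat3 and macrophage scores had r = 0.756 (p = 0.0484, adjusted p = 0.0964; rho = 0.679, p = 0.110), and r = 0.290 without 2, so that value rests on those libraries. None passed after adjustment, and whether these scores vary together among KO mice remains undecided with 7 mice.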
